A study of Homo sapiens with 6 samples.

How the data were processed

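Single cells from skin of 6 donors with acne were measured by droplet RNA sequencing, each donor giving a lesional and a non-lesional punch biopsy, so that 12 libraries in 2 lesion states were compared. Per the labels, epidermis and dermis were digested separately, cells were captured on a 10x Chromium, and reads were aligned with STAR to hg38. Versions, the annotation and the cell filters are not stated there. The deposited table of each donor holds the natural log of 1 plus the count of a gene scaled to 10000 counts per cell, for 29390 genes. The scaling was checked in every cell, and the count total of each cell was recovered from it. In donors 2 and 3 the recovered counts were whole, within 0.01, in 100% of cells. In donors 1, 4, 5 and 6 they were not whole, and most lay just under a whole number, as after a subtraction of ambient RNA. How the authors made these values is not stated. The 2 lesion states of a donor were alike in this. Donors 2 and 3 and donors 1, 4, 5 and 6 were therefore treated as 2 processing batches, and values within each batch stand beside pooled values of some leading genes and shares.

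The authors also deposited a donor-by-lesion average table of 25317 genes, whose unit is a normalized signal (mean count per cell after a depth adjustment that is not stated), and tables of the subtypes of 5 cell classes, which hold estimated counts summed over all donors and both lesion states. The average table served only as an alternative for the comparison of all cells, and 27 of its gene names had turned into dates. Subtype tables have no replicate and are given as CPM, counts scaled to the column total, without a test.

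Cells with at least 200 genes and at most 20% mitochondrial counts were kept, 58831 of 62168. Doublets were called with Scrublet in scanpy 1.11.5, which removed 385 cells. Of these, 358 came from 1 lesional library and 0 to 6 from each of the other 11, so that the caller removed few cells outside that library, and 58446 cells were used. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2), which gave 57 clusters. Donors were not integrated. A cluster took the name of the best-scoring of 14 cell classes with fixed markers if at least 3 markers were detected in 25% of its cells at a log2 fold of 1 against the other cells. It stayed unnamed if its 10 leading genes held more markers of another class, if another qualifying class scored within 0.5, or if its cells had a median depth under 1/3 of their own library's and none of the class's markers among those 10 genes. The last rule left out 3 clusters, the largest, of 1534 cells, with 9 keratinocyte markers detected. Such classes are called keratinocyte-like and so on. For the tests, 37 genes that are sex-linked or present in some people only were left out, and 29353 were kept.

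Since the values are logged and in 4 donors derive from counts that are not whole, no count model was fitted. The planned edgeR and DESeq2 tests and their normalizations were not run, and the fallback written for normalized values was used. For each class, CP10K (counts per 10000 counts of a cell) was averaged over the cells of a donor and lesion state with at least 20 cells in both states, in at least 3 donors. limma 3.58.1 (R 4.3.3) was fitted to log2(CP10K + 0.1) of the genes with a mean of at least 0.1, with the donor as replicate block and a trended, robust empirical Bayes variance. Benjamini-Hochberg adjustment ran over the genes tested in a class at a threshold of 0.05. The same donor gave both biopsies of a pair, and the counts with no replicate block stand beside the results, from 0 genes in fibroblast-like cells to 810 in keratinocyte-like cells. Of the 35 gene lists, those with at least 4 measured members were tested with camera at a preset correlation of 0.01 on the same log2 values (the plan named voom, which needs counts), with Benjamini-Hochberg adjustment over the lists of a class. Estimated correlations and fry were alternatives. Class shares, changes of lists and shares of cells with a TREM2 UMI were compared by exact two-sided paired permutation tests over donors (scipy 1.17.1), for which the smallest p with 6 donors is 0.03125.

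The genes named were set by rule before the data were examined, as were the lists, markers, tests and the first set of alternatives. The rule takes, among genes past the threshold that moved the same way in every donor and reached 0.2 CP10K (20 CPM) in a state, the 10 largest rises and the 10 largest falls, then up to 4 members of each list that passed and up to 2 that did not. Genes of known interest are added whatever their value. Gene positions are from GENCODE 29.

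The fit was tested on simulated data, drawn from the fitted means and variances of each class with counting noise at its depth, in which some genes were changed by 1 or 2 log2 units in either direction. Genes were drawn independently of each other, and the fitted variances already held counting noise before more was added. The recoveries and false calls below may therefore differ from those of the real fits. With 6 donors in myeloid-like cells it recovered 71.4% of changes of 1 log2 unit and 100% of changes of 2, with 5.03% false calls. The share of false calls was 2.80% in T and NK-like, 2.99% in vascular endothelial-like, 6.43% in fibroblast-like, 7.57% in keratinocyte-like, 7.89% in lymphatic endothelial-like and 10.8% in mural-like cells and 5.92% over all cells, with 1 false call of 4 in gland-like cells and no call in mast-like cells. In T and NK-like cells the recovery was 24.2% and 90.1%, in vascular endothelial-like cells 54.0% and 97.6%, in fibroblast-like cells 83.3% and 100%, and in keratinocyte-like cells, with 4 donors, 96.7% and 100%. With 3 donors, recovery of 2 log2 units was 100% in mural-like, 67.9% in lymphatic endothelial-like, 0% in mast-like and 3.53% in gland-like cells. Alternatives changed the block, the filter on low values, the pseudocount, the cell minimum, the mitochondrial limit, the doublets, the clustering resolution and each donor. Others, added after the data were seen, changed the scaling, the weights, the doublet share and the processing batch. Melanocyte-like, B and plasma-like, Schwann-like, sebocyte-like and red blood cell-like classes had enough cells in both states in fewer than 3 donors and were not tested for genes.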

Results

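Transcripts of single cells were counted in lesional and non-lesional skin of the same 6 donors with acne, and the comparisons ask which cells and genes differ between a lesion and unaffected skin of the same person. The 12 libraries held 582 to 12909 cells after filtering. Median depth per cell ranged from 1279 UMIs (unique molecular identifiers) in the non-lesional library of donor 3 to 18142 in the lesional library of donor 1. In all, a library held between 2715180 and 134492000 UMIs. Levels are given as CP10K, the mean over the cells of a class of the counts per 10000 counts of a cell, with the SD over donors. Changes are log2 ratios of lesional to non-lesional skin with the SE of the limma fit, and adjusted p values are limma's with Benjamini-Hochberg adjustment.

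Myeloid-like cells made up 13.3% ± 9.11 (SD, n = 6) of lesional and 7.24% ± 2.58 of non-lesional cells, and T and NK-like cells 13.9% ± 5.88 and 9.23% ± 6.44. Melanocyte-like cells, the pigment cells of the epidermis, made up 0.353% ± 0.201 of lesional and 1.42% ± 1.88 of non-lesional cells. Neither these differences nor those of the other 11 classes passed. The myeloid-like difference was 6.02 percentage points ± 7.68 (SD), higher in 5 of 6 donors, with an exact paired permutation p of 0.0625 and an adjusted p of 0.4375 over 14 classes. It was 5.85 ± 2.57 in donors 2 and 3 and 6.11 ± 9.80 in donors 1, 4, 5 and 6, and 3.14 without donor 4. The melanocyte-like difference had the same exact p, 0.0625, was lower in 5 of 6 donors and shrank from -1.07 points to -0.280 without donor 4. The T and NK-like difference was 4.68 points ± 10.1 (exact p = 0.3125), 11.75 ± 2.32 in donors 2 and 3, 1.14 ± 10.9 in donors 1, 4, 5 and 6, and 8.39 without donor 1. Fibroblast-like cells made up 16.7% ± 6.89 and 16.5% ± 12.4, keratinocyte-like cells 19.2% ± 26.2 and 21.4% ± 22.1, and vascular endothelial-like cells 13.2% ± 10.2 and 14.4% ± 11.9. Of the smaller classes, mural-like cells (pericytes and smooth muscle) held 3.96% and 4.74%, eccrine and other gland-like cells 1.08% and 6.28% (30.7% in 1 non-lesional biopsy, and a difference of -0.161 points without donor 4), lymphatic endothelial-like cells 1.02% and 1.22% (higher in lesions in 5 of 6 donors), and mast-like cells 0.505% and 0.494%. A class named for its haemoglobin genes held 4.18% and 1.98%. Its larger cluster, of 713 cells, had HBA2, HBA1 and HBB beside IGHA1, S100P, MMP7 and SOX9 among its 10 leading genes. Of those cells 88.92% came from the lesional library of donor 5. A cluster of 156 cells had 1 haemoglobin gene, HBB, among its 10 leading genes beside SOX9, CST6, CLDN1 and the keratins KRT2, KRT80, KRT6B and KRT77. The share of the class is therefore not one of red blood cells alone. Sebocyte-like cells, the lipid cells of the sebaceous gland, were found in 1 non-lesional biopsy and in 0 of 31185 lesional cells, which allows a share of up to 0.00962%, counting error only. That limit covers the named class only. Cluster 25, which stayed unnamed, had KRT79 and MGST1 of the sebaceous lipid list among its top genes. It held 240 lesional and 736 non-lesional cells, so that a lack of sebaceous cells in lesions is not shown. Clusters without a class name held 12.2% ± 8.02 and 14.7% ± 12.9. The cells of a digested biopsy need not be in the proportions of the tissue, and the smallest p that 6 pairs allow is 0.03125. Adjusted over 14 classes, a class could pass only if most classes reached that p, so that the lack of a pass does not show equal shares.

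**Figure D1:**
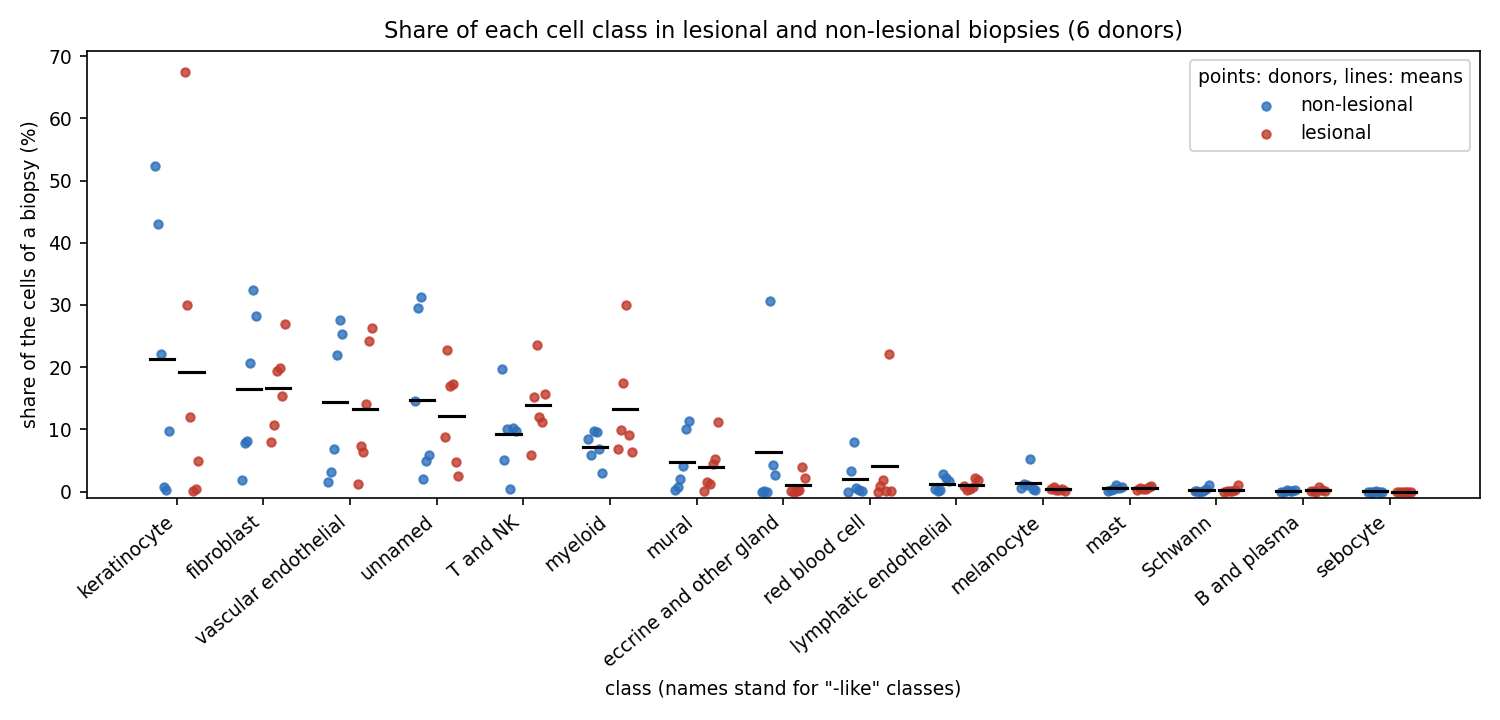
Share of each cell class among the cells of a biopsy, in percent, for 6 donors (points, blue for non-lesional and red for lesional) with the mean of each lesion state (black line). Myeloid-like cells averaged 13.3% in lesional and 7.24% in non-lesional biopsies, with overlapping donors.

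Keratinocyte-like cells of lesions carried more transcripts of the keratins of wounded and stressed epidermis and fewer of cornified layer genes. KRT6A, a keratin that epidermis makes after injury, reached 70.2 CP10K ± 25.1 in lesional and 8.04 ± 6.8 in non-lesional cells (log2 change 3.58 ± 0.715, n = 4 donors, adjusted p = 0.0496). LOR, which encodes loricrin, the main protein of the cornified envelope, fell from 14.1 CP10K ± 13.8 to 1.69 ± 2.36 (log2 change -3.64 ± 0.426, adjusted p = 0.00741). FLG2 and FLG, the filaggrins that bundle keratin in the outer layers, fell by 3.42 ± 0.232 and 3.32 ± 0.427 on the log2 scale. Basal keratins moved the other way, with KRT14 up by 1.68 ± 0.243 and KRT5 by 1.35 ± 0.116.

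By list, 12 of 19 cornified envelope genes fell and none rose, and 14 fell when adjusted over the list alone. Their median log2 change was -0.99, with a camera adjusted p of 1.66e-08 that was 0.349 with an estimated correlation. Among them were CDSN (-2.66) and the kallikreins KLK5 (-1.34) and KLK7 (-0.76), proteases that loosen corneocytes. Of 8 stress and wound keratin genes, 4 rose and 4 rose adjusted over the list alone, with KRT6C at 3.37, KRT16 at 2.60 and SPRR1B at 0.98 (camera adjusted p = 1.68e-05, and 0.349 with an estimated correlation). The inflammatory and antimicrobial list had a median of 2.22, with 1 of 13 members, SERPINB3 (2.42), past the threshold and 1 adjusted over the list alone (camera adjusted p = 3.9e-07, and 0.349 with an estimated correlation). S100A8 and S100A9, which form calprotectin, were at 302 CP10K ± 95.6 and 194 ± 62.6 in lesional cells and at 29.9 ± 25.1 and 20.6 ± 18.1 in non-lesional cells, with adjusted p of 0.0591 and 0.0683, so that neither passed. Of 16 cholesterol synthesis genes, 8 fell, also adjusted over the list alone, with a camera adjusted p of 0.00779 and 0.349 with an estimated correlation. Of 13 glycolysis and hypoxia genes, 6 rose and 7 adjusted over the list alone, ENO1 (1.26) and PKM (1.05) among them (camera adjusted p = 0.000137, and 0.349 with an estimated correlation). The basal adhesion list had 4 rises, with ITGB4 (1.19) and ITGA6 (0.91), and 1 fall, and 5 and 2 adjusted over the list alone (camera adjusted p = 0.0143, and 0.349 with an estimated correlation). Other large rises were IFITM3, an interferon-induced antiviral factor (2.54 ± 0.171, adjusted p = 8.52e-06), TYMP (2.55), AKR1B10 (3.09), S100A7A (3.07) and SERPINB1 (2.49), and other large falls C1orf68 (-3.15), KRT77 (-3.04), SERPINA12 (-2.90), LCE1C (-2.51) and ASPRV1 (-2.36). The fibroblast markers COL3A1 (0.68) and DCN (0.50) also rose, with 2 of 5 members past the threshold and 2 adjusted over the list alone (camera adjusted p = 0.00779, and 0.349 with an estimated correlation).

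In all, 552 of 7573 genes rose and 1291 fell in keratinocyte-like cells, against a median log2 change of all genes of -0.105. With median centring, 1020 rose and 848 fell, so that the balance of rises and falls turns with the scaling, and no gene named here changed sign. The largest cluster differed between the states, cluster 10 with KRT6C, KRT16 and KRT6A on top holding 45.1% ± 4.69 of lesional cells (n = 4 donors with at least 20 cells) and cluster 14 with KRT1, KRT10 and LGALS7B holding 56.7% ± 13.3 of non-lesional cells (n = 6). KRT6A changed by 3.00 in donors 2 and 3 and by 4.15 in donors 1 and 6, and LOR by -4.27 and -3.02. With no replicate block 810 genes passed, without donor 1 993, in donors 1 and 6 alone 472 and in donors 2 and 3 alone 128. With no filter on low values 0 genes passed in limma, with 4283 at an unadjusted p under 0.05.

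Myeloid-like cells of lesions held more transcripts of lipid-handling macrophages and fewer of dendritic and Langerhans cells. TREM2, a lipid-sensing receptor of macrophages, was at 0.532 CP10K ± 0.327 in lesional and 0.152 ± 0.118 in non-lesional cells (log2 change 1.31 ± 0.263, n = 6, adjusted p = 0.00737), higher in 6 of 6 donors. GPNMB, a glycoprotein of lipid-laden macrophages, rose by 1.80 ± 0.304, LPL, which hydrolyses triglycerides, by 1.88 ± 0.274, and CTSD, a lysosomal protease, by 1.94 ± 0.244. CD1C, which presents lipid antigens on dendritic cells, fell by 1.97 ± 0.285 on the log2 scale, and CD207, the langerin of Langerhans cells, by 1.24 ± 0.298. These falls do not cover cluster 32, which stayed unnamed and outside the class. Its top genes held LAMP3 and CCR7 of the dendritic cell list beside the B cell markers MS4A1 and CD79A. Pooled over donors and not tested, it held 435 lesional cells (1.395% of that state) and 37 non-lesional cells (0.136%). Cluster 46, with CD207 and CD1A among its top genes, stayed unnamed as well, with 63 lesional and 67 non-lesional cells. The share of myeloid-like cells with a TREM2 UMI was 11.9% ± 4.53 in lesional and 3.07% ± 2.62 in non-lesional skin, a difference of 8.85 points ± 6.03 (higher in 6 of 6 donors, exact p = 0.03125, the smallest 6 pairs allow).

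Among the 20 measured members of the lipid-handling macrophage list, 9 rose and none fell, and 16 rose adjusted over the list alone. Their median was 1.20, with a camera adjusted p of 1.41e-17 that was 0.136 with an estimated correlation, and they included NR1H3, the sterol-sensing receptor LXR alpha (1.89), and CTSB (1.17). APOE (2.45 ± 0.585, adjusted p = 0.132) and SPP1 (3.24 ± 0.957, adjusted p = 0.222) did not pass. Of 12 monocyte and neutrophil genes, 5 rose and 11 adjusted over the list alone, with VCAN (2.11), FCN1 (1.14), CD14 (1.01) and LYZ (0.92) (camera adjusted p = 3.9e-15, and 0.136 with an estimated correlation). Of 12 Langerhans and dendritic cell genes, 5 fell and 7 adjusted over the list alone, CD83 (-0.83) and CD1A (-1.11) among them (camera adjusted p = 3.08e-08, and 0.136 with an estimated correlation). Of 8 MHC class II genes, 3 fell, CD74 (-0.45), HLA-DPA1 (-0.61) and HLA-DPB1 (-0.56), and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.000187, and 0.237 with an estimated correlation). Glycolysis and hypoxia genes rose in 4 of 13 cases, HIF1A (1.38) and HK2 (1.09) among them, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.00147, and 0.297 with an estimated correlation). The resident macrophage list did not pass (adjusted p = 0.317), though C1QB (1.23), CD163 (1.55) and C1QC (0.69) of its 13 members rose, as they did adjusted over the list alone. Outside the lists, SLC11A1 (2.37), AQP9 (2.32) and LILRB1 (1.97) rose most, and CD1E (-1.79), P2RY14 (-1.77) and IL1R2 (-1.55) fell. IL1B (-0.43 ± 0.71), CXCL8 (0.19 ± 0.42), CCL2 (0.46 ± 0.791), CCL18 (1.80 ± 0.947) and CXCL10 (1.18 ± 0.517) did not pass. Cluster 39, with IL1B, CCL3 and CCL4 among its top genes, stayed unnamed and outside the class, with 115 lesional and 186 non-lesional cells.

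Markers of other cells moved beside these lists in the myeloid-like class. Eccrine gland markers had a median of -1.15 with 0 of 5 members past the threshold, nor any adjusted over the list alone (camera adjusted p = 0.00677, and 0.490 with an estimated correlation), and turned direction without donor 4 (adjusted p = 0.883). Keratinocyte markers had a median change of -0.77 with 0 of 8 members past the threshold in limma, nor any adjusted over the list alone, and a camera adjusted p of 0.00032 (0.413 with an estimated correlation). Fibroblast markers had a median of 0.59 with 1 of 6, LUM (1.15), past it, and also adjusted over the list alone (camera adjusted p = 0.0432, and 0.49 with an estimated correlation). Fibrillar collagen genes rose in 3 of 17 cases, also adjusted over the list alone, FN1 (1.24) and SPARC (1.19) among them (camera adjusted p = 0.000564, and 0.49 with an estimated correlation). In all, 177 of 7928 genes rose and 71 fell. The mix of clusters differed as well. Cluster 4, with SPP1, APOC1 and MMP12 on top, held 34.4% ± 31.3 of lesional and 8.63% ± 11.8 of non-lesional cells. Cluster 15, with CD1C and HLA-DPB1 among its top genes, held 13.8% ± 6.94 and 31.3% ± 33.5, and cluster 37, with CD207 and CD1A, 8.44% ± 12.4 and 17.6% ± 26.7. TREM2 changed by 1.39 in donors 2 and 3 and by 1.28 in donors 1, 4, 5 and 6, LPL by 1.63 and 2.01 and CD1C by -1.73 and -2.09. CD207 changed by -0.35 and -1.68 in the same batches, CD1A by -0.32 and -1.51. SLC11A1 changed by 1.17 and 2.97, HIF1A by 0.35 and 1.89 and SPP1 by 1.04 and 4.34. With no replicate block 1 gene passed and TREM2 did not, without donor 1 118, without donor 4 157, without donor 5 155 and in donors 2 and 3 alone 63. With no filter on low values 0 passed in limma, with 1605 at an unadjusted p under 0.05.

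Thinned to 1000 UMIs per cell, 3.52% ± 1.96 of lesional and 0.951% ± 0.57 of non-lesional myeloid-like cells held a TREM2 UMI, a difference of 2.57 points ± 1.87 in 6 of 6 donors (exact p = 0.03125). The median depths were 5794 and 4550 UMIs before thinning, and 374 and 450 shallower cells were left out. As background, 0.161% ± 0.257 of lesional T and NK-like cells held a TREM2 UMI, at a median depth of 2316, and 0 of 1898 non-lesional ones at 1519, which allows up to 0.158%, counting error only. In the subtype table, TREM2 was at 137.9 CPM in the TREM2 macrophages and 41.3 in the next subtype. Of all 177 rising genes, 46.3% were highest in TREM2 macrophages, against 20.2% of the genes tested, and 29.9% in M1-like macrophages, against 15%. Of the 71 falling genes, 38.0% were highest in Langerhans cells, 25.4% in CD1C dendritic cells and 21.1% in LAMP3 dendritic cells, against 24.7%, 4.15% and 10.7% of the genes tested. The unnamed cluster 32, with LAMP3 among its top genes and 435 lesional and 37 non-lesional cells, did not enter these falls. Nor did the unnamed cluster 46, with CD207 and CD1A among its top genes. The subtype tables were pooled by the authors over the same donors and both lesion states and have no replicates.

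**Figure D2:**
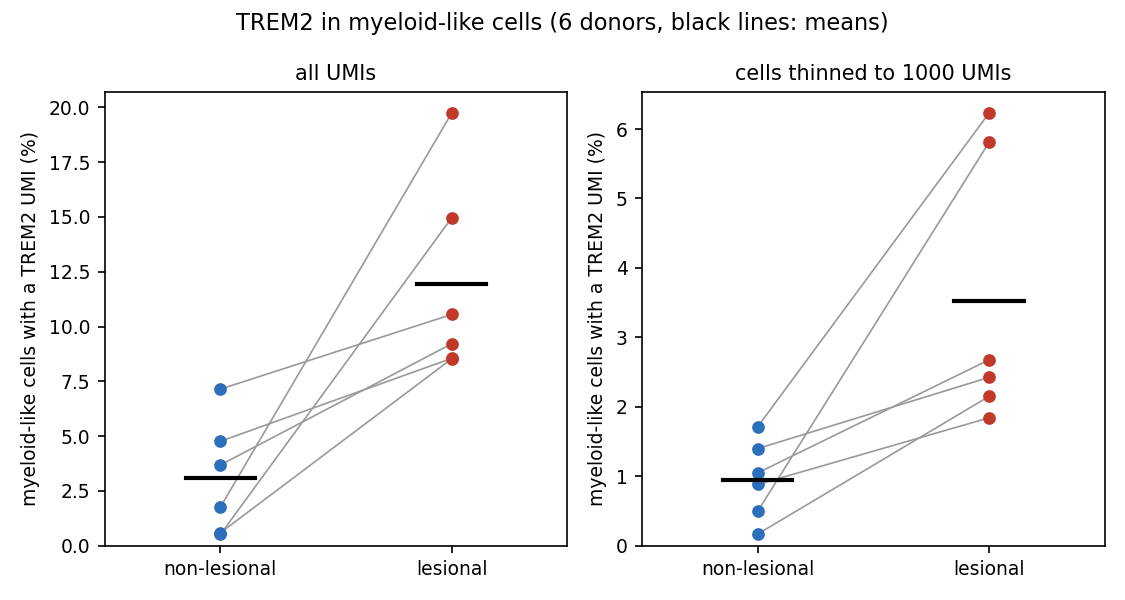
Share of myeloid-like cells with a TREM2 UMI, in percent, in non-lesional and lesional skin of 6 donors (points joined by donor, black lines are means), with all UMIs on the left and cells thinned to 1000 UMIs on the right. The share was higher in lesional skin in 6 of 6 donors, with means of 11.9% against 3.07% and, thinned, 3.52% against 0.951%.

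In vascular endothelial-like cells of lesions COL4A1 and COL4A2, the chains of basement membrane collagen, rose by 1.52 ± 0.237 and 1.59 ± 0.208 (n = 6, adjusted p = 0.00389 and 0.000346), and COL4A1 was at 10.6 CP10K ± 5.35 in lesional and 4.65 ± 4.07 in non-lesional cells. HSPG2, the basement membrane proteoglycan perlecan, rose by 1.40 ± 0.179 and THBS1 by 1.98 ± 0.313. CLU, a secreted chaperone, fell from 13.8 CP10K ± 5.45 to 4.73 ± 2.15 (log2 change -1.59 ± 0.156, adjusted p = 1.07e-05). The adhesion molecules SELE (0.01 ± 0.172) and VCAM1 (0.16 ± 0.264) and the venular chemokine receptor ACKR1 (-0.39 ± 0.198) did not pass.

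Of 18 type I interferon genes, 1 fell, IFIT3 (-1.43), and 5 fell adjusted over the list alone, with a median of -0.28 and a camera adjusted p of 3.94e-08 (0.104 with an estimated correlation). Of 8 MHC class II genes, 4 fell, also adjusted over the list alone, HLA-DRA (-0.79) and CD74 (-0.65) among them (camera adjusted p = 2.22e-06, and 0.191 with an estimated correlation). Of 13 angiogenesis genes, 2 rose and 7 adjusted over the list alone (camera adjusted p = 3.77e-07, and 0.104 with an estimated correlation). The scar list had 2 rises among 6 members, CTHRC1 (1.09) among them, and 4 adjusted over the list alone (camera adjusted p = 0.000186, and 0.104 with an estimated correlation). The endothelial activation list fell by its test (camera adjusted p = 2.65e-06, and 0.156 with an estimated correlation) with 2 of 12 members past the threshold, SOCS3 (-1.18), a brake on cytokine signalling, and CD74, and adjusted over the list alone 4 fell and 1 rose. IRF1, an interferon-induced transcription factor (-1.09), was the 1 member of 13 of the interferon gamma list to fall, also adjusted over the list alone (camera adjusted p = 0.0012, and 0.169 with an estimated correlation). Other falls were LIFR (-1.40), CX3CL1 (-1.26), MYC (-1.10) and TIMP3 (-1.05). Beside these, the monocyte and neutrophil list had 3 rises among 7 members, S100A9 (1.49) and THBS1 among them, and 6 adjusted over the list alone (camera adjusted p = 7.03e-06, and 0.104 with an estimated correlation). The eccrine gland markers had a median of -1.59 and fibroblast markers one of -0.60, with 0 of 5 and 0 of 6 members past the threshold in limma, nor any adjusted over the list alone (camera adjusted p = 3.42e-07 and 0.0012, and 0.169 and 0.282 with an estimated correlation).

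In all, 59 of 8470 genes rose and 30 fell in vascular endothelial-like cells, against a median of all genes of 0.139, and with median centring 33 rose and 29 fell. Cluster 2, with ACKR1, PLVAP and SELE on top, held 39.7% ± 18.2 of lesional cells, and cluster 1, with CCL14, IL6 and CSF3 on top, 28.8% ± 30.7 of non-lesional cells. COL4A1 changed by 0.70 in donors 2 and 3 and 1.93 in donors 1, 4, 5 and 6, CLU by -1.51 and -1.62, and S100A9 by 0.53 and 1.97. With no replicate block 0 genes passed in limma (799 at an unadjusted p under 0.05), without donors 1, 2, 3 and 4 in turn 29, 45, 32 and 51, and in donors 2 and 3 alone 15 and donors 1, 4, 5 and 6 alone 5. When no filter was set on low values 0 passed, with 1449 at an unadjusted p under 0.05.

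In fibroblast-like cells of lesions GSN, the actin-severing protein gelsolin, fell from 15.2 CP10K ± 7.99 to 5.91 ± 4.93 (log2 change -1.63 ± 0.202, n = 6, adjusted p = 0.00609), ID1, an inhibitor of differentiation factors, fell by 1.56 ± 0.211 and LTBP4, which holds latent TGF-beta in the matrix, by 1.41 ± 0.207 on the log2 scale. The Wnt pathway modulators DKK3, SFRP1 and RSPO1 fell by 1.11 ± 0.168, 1.07 ± 0.198 and 1.05 ± 0.179. CHI3L1, a chitinase-like secreted protein, rose by 1.44 ± 0.238 and CTSB, a lysosomal protease, by 1.09 ± 0.184. MMP1 (2.58 ± 0.779, adjusted p = 0.279) and MMP3 (2.19 ± 0.68, adjusted p = 0.283), the collagenase and stromelysin, were higher in 5 of 6 donors and did not pass, nor did POSTN (0.56 ± 0.397), COL1A1 (0.47 ± 0.239), CXCL12 (-0.18 ± 0.184) or CCL19 (0.44 ± 1.04).

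Of the other genes named, MT1G (1.35) and WIPI1 (0.95) rose and ENHO (-1.49), PRELP (-1.41), TXNIP (-1.33) and HSPA2 (-1.01) fell. The cell cycle list passed its test with a median of 0.59, 0 of 14 members past the threshold in limma and 3 adjusted over the list alone (camera adjusted p = 1.47e-06, and 0.338 with an estimated correlation). The fibrillar collagen list had a median of 0.46 with 0 of 20 members past it, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 3.98e-05, and 0.45 with an estimated correlation). The metalloproteinase list had a median of 0.30 with 0 of 13 members past it and 2 adjusted over the list alone (camera adjusted p = 0.00141, and 0.277 with an estimated correlation), and neutrophil chemokines a median of 0.49 with 0 of 6 and 3 (camera adjusted p = 0.000233, and 0.277 with an estimated correlation). At an unadjusted p under 0.05 stood 1127 of the 8909 genes tested. Beside these, keratinocyte markers had a median of -1.12 with 0 of 8 members past the threshold and 2 adjusted over the list alone (camera adjusted p = 7.31e-06, and 0.338 with an estimated correlation). Eccrine gland markers had a median of -1.60 with 0 of 5 and 0 (camera adjusted p = 0.00153, and 0.392 with an estimated correlation). In all, 4 genes rose and 10 fell, and with median centring 24 rose and 23 fell, so that the balance turns with the scaling. The mix of clusters differed as well. Cluster 6, with MMP3 and MMP1 on top, held 47.4% ± 30.3 of lesional and 26.5% ± 37.6 of non-lesional cells. Clusters 3 and 5, both with WIF1 among their top genes, held 9.78% ± 14.6 and 11.6% ± 8.46 of lesional and 20.7% ± 35.4 and 20.01% ± 15.9 of non-lesional cells. GSN changed by -1.82 in donors 2 and 3 and -1.53 in donors 1, 4, 5 and 6, CTSB by 0.46 and 1.41, and MMP1 by 0.33 and 3.70. None of the 4 rises, CHI3L1, CTSB, MT1G and WIPI1, passed with a pseudocount of 1 or 0.01 or without donor 4. With no replicate block 0 genes passed in limma (455 at an unadjusted p under 0.05), without donors 2, 3, 4 and 6 in turn 43, 6, 7 and 4, and in donors 1, 4, 5 and 6 alone 52. Lifting the filter on low values left 0, with 1690 at an unadjusted p under 0.05.

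T and NK-like cells of lesions carried more CXCL13, the chemokine that draws B cells, at 1.69 CP10K ± 1.53 against 0.0394 ± 0.0839 (log2 change 3.20 ± 0.441, n = 6, adjusted p = 0.00574). LMNA, which encodes the nuclear lamins A and C, fell from 17.8 CP10K ± 8.75 to 8.26 ± 4.54 (log2 change -1.13 ± 0.154, adjusted p = 0.00179). PHLDA1, FOS, LGALS1 and VIM fell by 1.01 ± 0.149, 0.93 ± 0.127, 0.92 ± 0.137 and 0.82 ± 0.115 on the log2 scale, FOS being an immediate-early gene and VIM the filament protein vimentin. IL17A (0.09 ± 0.776), IFNG (0.66 ± 0.723), GZMB (0.14 ± 0.393) and FOXP3 (0.12 ± 0.283), the signature genes of Th17, Th1, cytotoxic and regulatory T cells, did not pass.

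Of 16 dissociation stress genes (immediate-early and heat shock genes), 1 fell, FOS, and 4 fell adjusted over the list alone, with a median of -0.29. This list's call, at a camera adjusted p of 3.02e-08, was the only one of all classes to hold with an estimated correlation, at an adjusted p of 0.0382. The interferon gamma list had a median of 0.41 with 0 of 10 members past the threshold in limma, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.0375, and 0.586 with an estimated correlation). The Th17 and regulatory T cell lists did not pass, with adjusted p of 0.638 and 0.346, 0 of 8 members each past the threshold and, adjusted over the list alone, 1 Th17 gene lower and 1 regulatory T cell gene higher. At an unadjusted p under 0.05 stood 582 of the 7864 genes tested, and 1 rose and 5 fell after adjustment. Eccrine gland markers had a median of -0.81 with 0 of 5 members past the threshold, nor any adjusted over the list alone (camera adjusted p = 0.0181, and 0.586 with an estimated correlation), and turned direction without donor 4 (adjusted p = 0.700). The monocyte and neutrophil list had a median of 1.01 with 0 of 6 members past the threshold and 1 adjusted over the list alone, and the keratinocyte inflammatory list one of 0.95 with 0 of 5 and 0 (camera adjusted p = 0.0181 and 0.0211, and 0.586 for both with an estimated correlation). CXCL13 was at 0 in non-lesional cells of 4 of 6 donors, so that the size of its change is set by the pseudocount. It was 1.16 with a pseudocount of 1 and did not pass. CXCL13 was also among the top genes of the fibroblast-like cluster 6. That cluster held 47.4% ± 30.3 of lesional and 26.5% ± 37.6 of non-lesional fibroblast-like cells. Free RNA of fibroblasts in T and NK-like cells was not tested for CXCL13 and stays open. CXCL13 changed by 4.16 in donors 2 and 3 and 2.72 in donors 1, 4, 5 and 6, and LMNA by -1.32 and -1.03. With median centring 3 genes rose and 5 fell, without donor 6 10 genes passed, in donors 2 and 3 alone 17, and in donors 1, 4, 5 and 6 alone 0. With no replicate block 0 passed in limma (292 at an unadjusted p under 0.05), and with no filter on low values 0 (918).

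**Figure D3:**
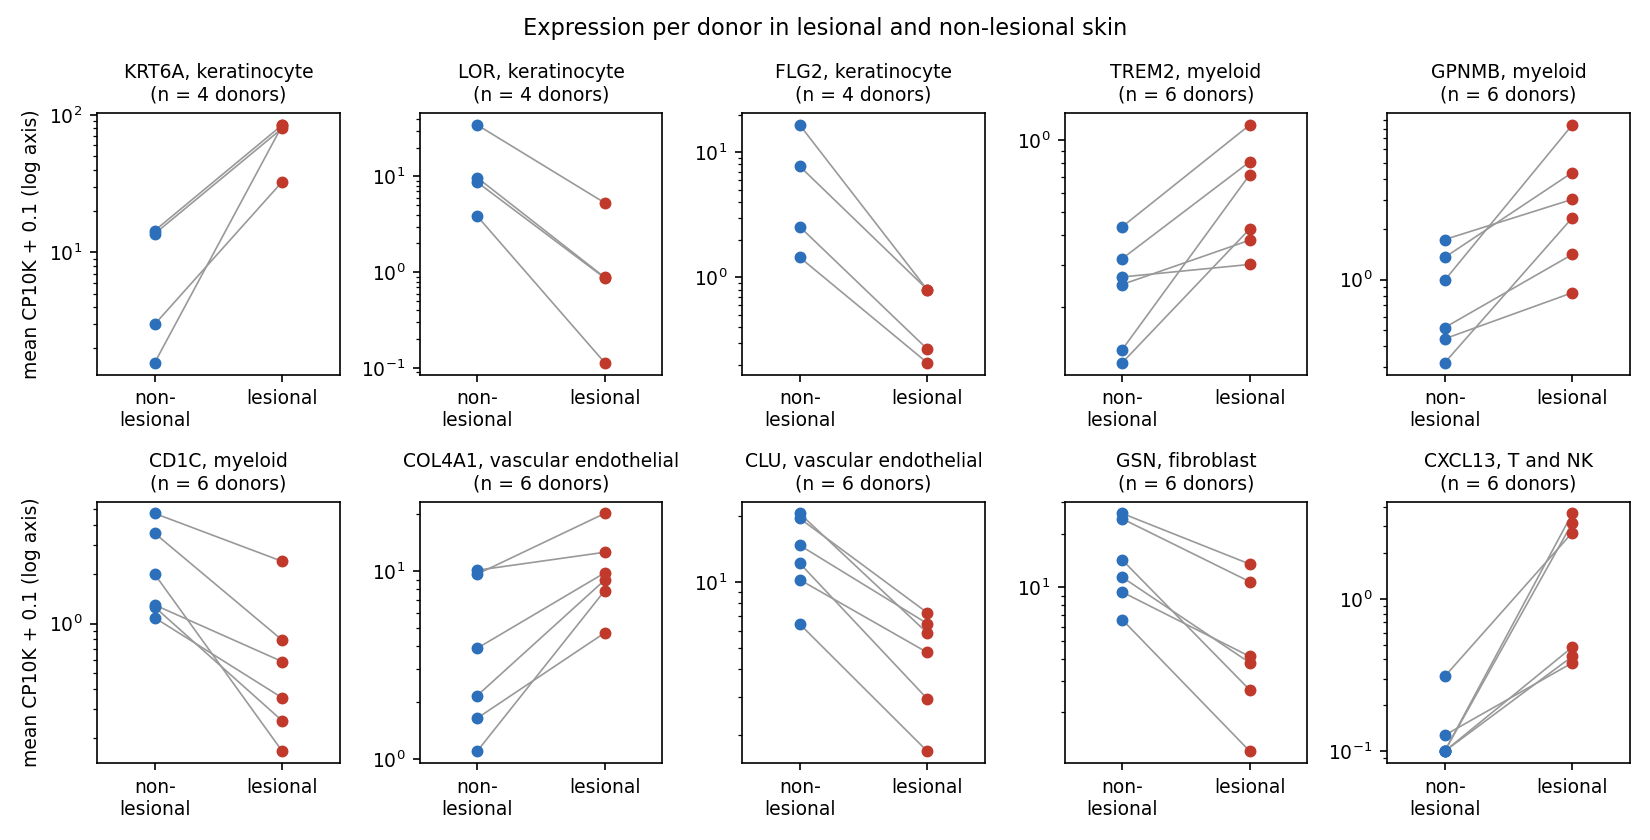
Expression of 10 genes in their class in non-lesional (blue) and lesional (red) skin, each point a donor and each line a pair, as mean CP10K plus 0.1 on a log axis. KRT6A rose and LOR and FLG2 fell in 4 of 4 donors in keratinocyte-like cells, and the other genes moved one way in 6 of 6 donors.

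Mural-like cells, which wrap vessels, could be compared in donors 4, 5 and 6, where 18 of 8935 genes rose and 3 fell. PI15, a secreted peptidase inhibitor, rose by 2.72 ± 0.337, CCL19, a chemokine that guides T cells and dendritic cells, from 8.2 CP10K ± 4.64 to 45.7 ± 31.4 (log2 change 2.31 ± 0.279, n = 3, adjusted p = 0.00146) and COL4A1 by 2.09 ± 0.338. CCL2, the chemokine of monocytes, fell by 1.49 ± 0.282 on the log2 scale, and CH25H, which makes 25-hydroxycholesterol, by 1.90 ± 0.262. S100A9 (2.39 ± 0.301) and S100A8 (2.24 ± 0.324) rose as well. The mix of clusters differed, cluster 8, with RGS5 and ABCC9 on top, holding 68.7% ± 10.6 of lesional (n = 5 donors with at least 20 cells) and 45.3% ± 20.1 of non-lesional cells (n = 3). Cluster 18, with MYH11 and ACTA2 among its top genes, held 27.3% ± 10.2 and 44.0% ± 18.8. The fibrillar collagen list had 1 rise among 19 members, FN1 (1.58), and 9 adjusted over the list alone (camera adjusted p = 1.94e-11, and 0.393 with an estimated correlation). Complement genes C1R (1.59) and C1S (1.52) rose, 2 of 8 and 4 adjusted over the list alone (camera adjusted p = 0.000273, and 0.393 with an estimated correlation). Eccrine gland markers had a median of -1.94 with 0 of 5 members past the threshold in limma, nor any adjusted over the list alone (camera adjusted p = 6.08e-06, and 0.393 with an estimated correlation), and turned direction without donor 4 (adjusted p = 0.631). At an unadjusted p under 0.05 stood 602 genes. Without donors 4, 5 and 6 in turn 1, 3 and 296 genes passed, with no replicate block 0 (388 at an unadjusted p under 0.05), and with no filter on low values 0 (519).

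Lymphatic endothelial-like cells of donors 4, 5 and 6 raised 12 of 8980 genes and lowered 6. CCL21, the chemokine by which lymphatics draw dendritic and T cells, rose from 94.7 CP10K ± 40.5 to 305 ± 201 (log2 change 1.59 ± 0.193, n = 3, adjusted p = 1.8e-05), PDPN, the lymphatic glycoprotein podoplanin, by 1.61 ± 0.282 and TIMP1, an inhibitor of metalloproteinases, by 3.07 ± 0.248. EDN1, the vasoconstrictor endothelin, fell by 2.09 ± 0.395 on the log2 scale. S100A9 (2.82) and S100A8 (2.46) rose in 2 of 7 members of the monocyte and neutrophil list, 7 adjusted over the list alone (camera adjusted p = 5.21e-13, and 0.355 with an estimated correlation). Markers of other cells rose with them, COL3A1 (2.60) and COL1A2 (1.55) in 2 of 6 fibroblast markers, 5 adjusted over the list alone (camera adjusted p = 3.09e-10, and 0.355 with an estimated correlation), and CD3D (2.37), a T cell receptor chain. Cluster 55 of this class, of 16 cells, had the macrophage genes C1QC and FOLR2 beside CCL21 and PDPN among its top genes, and 93.75% of it came from 1 lesional library. Eccrine gland markers had a median of -2.18 with 0 of 5 members past the threshold, nor any adjusted over the list alone (camera adjusted p = 7.07e-07, and 0.460 with an estimated correlation), and turned direction without donor 4 (adjusted p = 0.341). Without donors 4 and 6 in turn 127 and 33 genes passed, and with no replicate block 3. With no filter on low values 0 passed in limma, with 629 at an unadjusted p under 0.05, and with summed counts 15 rose and 1 fell.

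In mast-like cells of donors 4, 5 and 6, 9 of 8319 genes rose and 3 fell. Donors 4 and 5 gave 24 and 20 lesional cells with 28444 and 32917 UMIs in all, so that levels there rest on few counts. The simulated fit recovered 0% of changes of 2 log2 units in this class. Of 4 arrangements of the lesion states 2 gave 12 genes, so that the number of calls is not set apart from chance. IL13, a type 2 cytokine, fell from 3.95 CP10K ± 2.23 to 0.847 ± 1.31 (log2 change -3.16 ± 0.705, n = 3, adjusted p = 0.00703), and CCL4L2, a chemokine, rose by 3.69 ± 0.793. Genes of other cells led the rest: 5 of 6 fibroblast markers rose, also adjusted over the list alone, with COL1A1 at 2.79 and DCN at 2.78 (camera adjusted p = 4.75e-25, and 0.233 with an estimated correlation), and the gland gene MUCL1 fell by 4.31 ± 0.859, the 1 of 5 eccrine markers past the threshold, 3 adjusted over the list alone (camera adjusted p = 1.87e-30, and 0.233 with an estimated correlation). In gland-like cells of the same donors 4 of 7189 genes rose and 4 fell. The mix of clusters differed here too, cluster 16 holding 74.2% ± 39.5 of lesional and 44.6% ± 8.55 of non-lesional cells (n = 3). Cluster 9 held 21.7% ± 34.5 of non-lesional cells, and 99.24% of its cells came from the non-lesional library of donor 4. SFRP1, a Wnt modulator, rose by 1.69 ± 0.379 (adjusted p = 0.0113), and the haemoglobin genes HBB (-4.62), HBA2 (-3.37) and HBA1 (-3.26), markers of red blood cells, fell. Clusters named for haemoglobin genes, with SOX9 among their leading genes, were outside the gland-like class. Whether these falls are of red blood cell RNA was not tested. With median centring 1 gene rose and 4 fell in gland-like cells, with summed counts 2 and 5, without donors 4 and 5 in turn 5 and 1 passed, and with no replicate block 4. In mast-like cells 8 genes passed with no replicate block. With no filter on low values 10 genes passed in mast-like cells and 0 in gland-like cells (521 at an unadjusted p under 0.05).

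Over all cells of a biopsy, where the mix of cell classes counts as well, S100A8 and S100A9 rose by 2.38 ± 0.383 and 2.27 ± 0.365 (n = 6, adjusted p = 0.0362 and 0.0341). MMP1, the interstitial collagenase, rose by 2.00 ± 0.295, LYZ, the lysozyme of myeloid cells, from 1.79 CP10K ± 0.685 to 5.91 ± 4.07 (1.54 ± 0.242) and CD163, a scavenger receptor of macrophages, by 1.26 ± 0.134. CST6, a protease inhibitor of the epidermis, fell by 2.13 ± 0.172 on the log2 scale and CLDN1, a tight junction protein, by 1.42 ± 0.17. Of 18 cornified envelope genes 1 fell, KLK7 (-0.89), and 15 fell adjusted over the list alone (camera adjusted p = 4.97e-13, and 0.193 with an estimated correlation). Of 20 fibrillar collagen and matrix genes 4 rose, CTHRC1 (1.30), FBN1 (1.10), SPARC (0.91) and TNC (0.86), and 11 adjusted over the list alone (camera adjusted p = 1.07e-07, and 0.34 with an estimated correlation). Of 9 monocyte and neutrophil genes 3 rose and 9 adjusted over the list alone (camera adjusted p = 1.07e-07, and 0.177 with an estimated correlation). Eccrine gland markers had a median of -2.0 and keratinocyte markers one of -0.78, with 0 of 5 and 0 of 8 members past the threshold in limma, nor any adjusted over the list alone (camera adjusted p = 0.0019 and 0.00145, and 0.348 for both with an estimated correlation). In all, 67 of 9230 genes rose and 30 fell, and with median centring 106 and 79. A pseudocount of 1 left 3 genes, and the authors' average table gave 440. S100A8 changed by 1.05 in donors 2 and 3 and 3.05 in donors 1, 4, 5 and 6, and CST6 by -2.29 and -2.04. Without donors 1, 2, 3, 5 and 6 in turn 241, 25, 3, 189 and 10 genes passed, with no replicate block 0 (598 at an unadjusted p under 0.05), and in donors 1, 4, 5 and 6 alone 3. When no filter was set on low values 0 passed, with 3305 at an unadjusted p under 0.05.

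**Figure D4:**
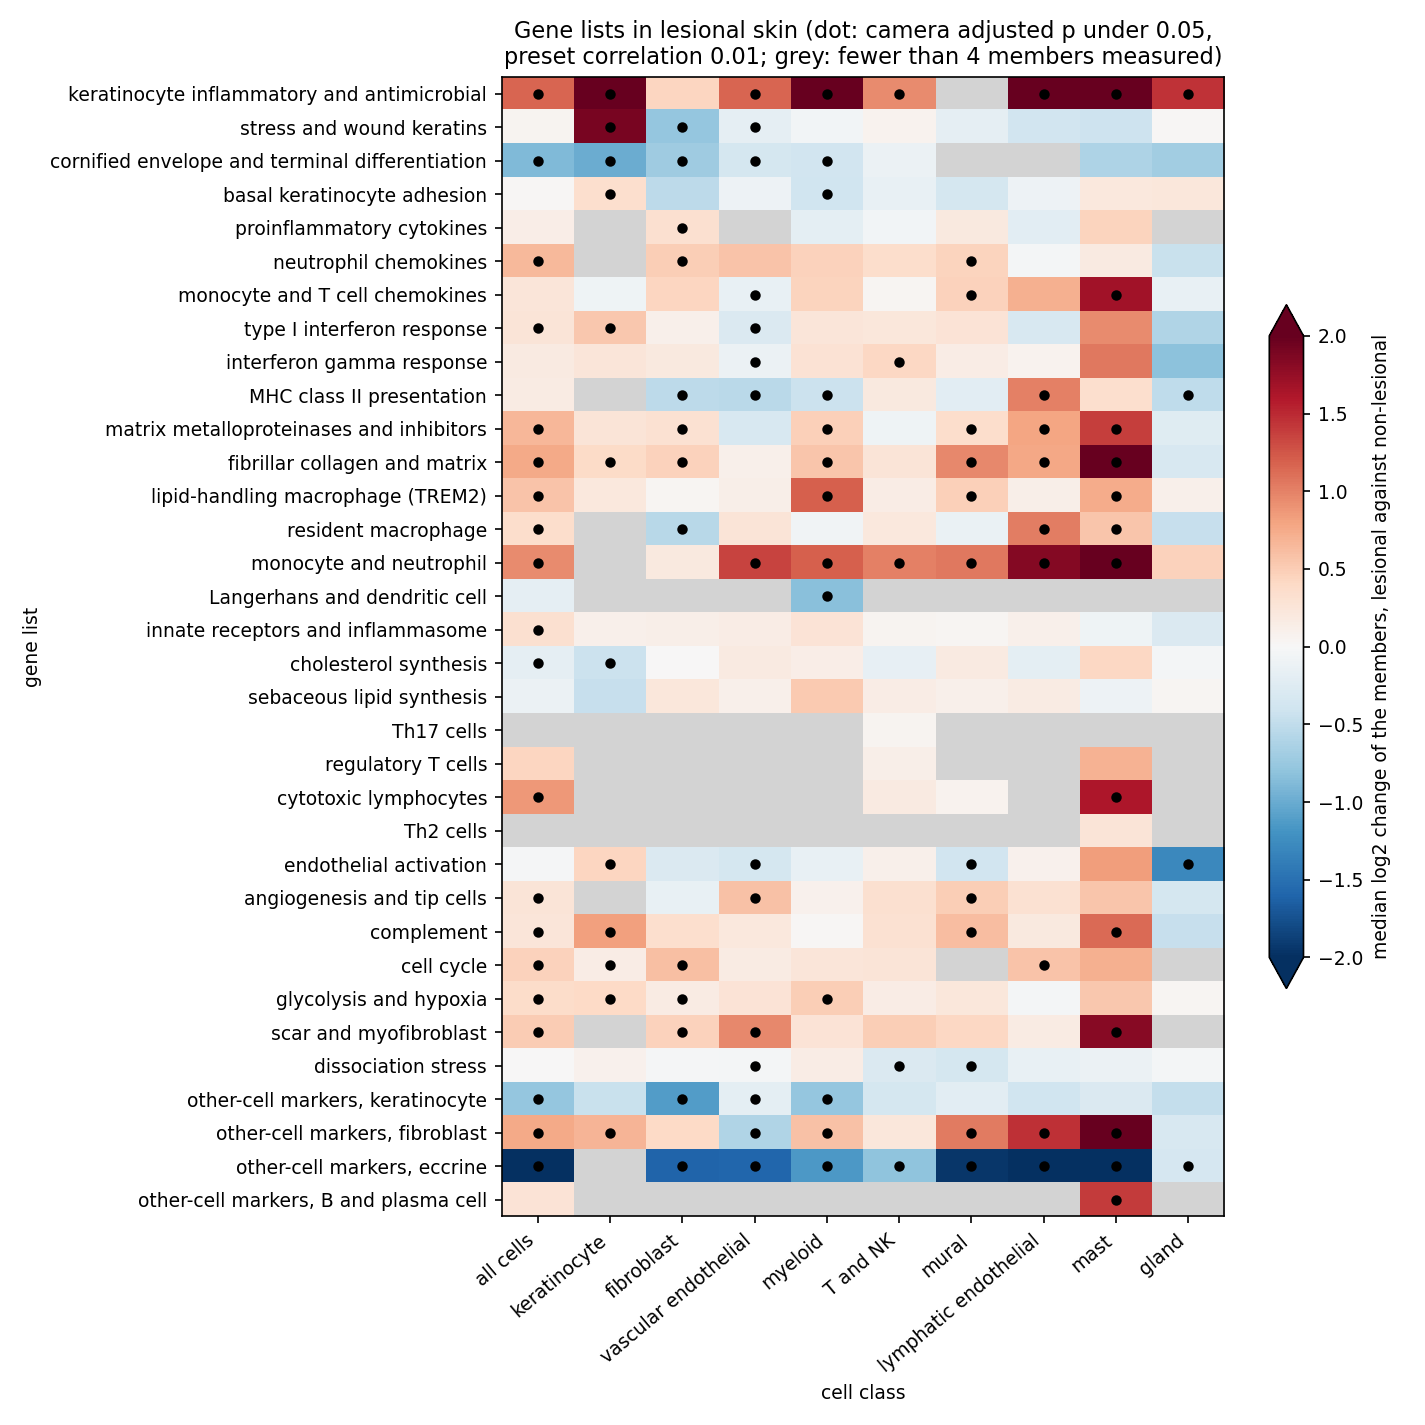
Median log2 change of the members of each gene list (vertical axis) in each cell class (horizontal axis), with a dot where camera's adjusted p at a preset correlation of 0.01 passed and grey where fewer than 4 members were measured. The lipid-handling macrophage list reached a median of 1.20 in myeloid-like cells and the cornified envelope list -0.99 in keratinocyte-like cells. With an estimated correlation 1 call held, the dissociation stress list in T and NK-like cells.

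List changes of 2 classes were compared within donors for 214 pairs, and none of the differences passed, with a smallest adjusted p of 0.334. The exact p could not fall below 0.03125 with 6 donors, or below 0.125 in the 70 pairs with 4. After adjustment a pair could pass only if nearly all pairs with 6 donors reached 0.03125, so that the lack of a pass says little. That smallest p was reached by 20 of the 144 pairs with 6 donors. Chance would give 4.5 for lists not chosen from these data, but the lists compared had passed in at least 1 of the classes. Pairs also share lists and donors, so that the 20 cannot be set against the 4.5. A change past the threshold in 1 class and not in another is therefore not shown to differ between them. CTSB rose in 4 classes, keratinocyte-like, fibroblast-like, myeloid-like and vascular endothelial-like cells, and S100A9 in 3, the vascular, lymphatic endothelial-like and mural-like cells.

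On hg38, TREM2 lies on chromosome 6 at 41158506 to 41163186 and KRT6A on chromosome 12 at 52487174 to 52493257, both on the minus strand. LOR lies on chromosome 1 at 153259700 to 153262122 and FLG2 at 152348735 to 152360006, both in the cluster of epidermal differentiation genes that also holds S100A9, at 153357854 to 153361027. COL4A1 lies on chromosome 13 at 110148963 to 110307233, CLU on chromosome 8 at 27596917 to 27615031, GSN on chromosome 9 at 121207794 to 121332843 and CXCL13 on chromosome 4 at 77511753 to 77611834. Counts of a gene are sums over its transcripts, with no split by exon.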

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

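The 3 tests of free RNA, the test of depth and the test of handling were chosen after the results they concern were seen; the test inside clusters was set before.

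S100A9 rose in vascular endothelial-like, mural-like and lymphatic endothelial-like cells of lesions, and S100A8 with it in the last pair, while neither the endothelial nor the mural lineage is a known main source of calprotectin, so that RNA set free by other cells was weighed. If it came from lesional keratinocytes or myeloid cells, other abundant transcripts of those cells should have risen in the ratio set by S100A9, and the median ratio of observed to predicted gain was 0.409 for keratinocytes, with donors from -1.94 to 1.42, and 0.144 for myeloid cells, with donors from -0.0887 to 2.34, which decides neither. Without CXCL8 and IL1B, which endothelial cells can also make, the ratio for myeloid cells was 0.117, with donor medians from 0.00459 to 0.392. It reached 4.47 in lymphatic endothelial-like cells of 1 donor, which held most of a cluster of 16 cells with macrophage genes. In donors whose counts were not whole, a subtraction of ambient RNA may have changed the ratio, so that it cannot decide there. The mural-like and lymphatic endothelial-like values come from such donors alone. In vascular endothelial-like cells of donors 2 and 3, with whole counts, the ratio was 0.00459 and 0.21. With CXCL8 and IL1B kept, it was -0.0887 and 0.138. These values argue against myeloid RNA as the whole cause in those cells of those donors only. Keratinocyte RNA, RNA of neutrophils, which the 14 classes do not include, and expression by the cells themselves stay open as possible explanations. Myeloid RNA stays open as well in the donors whose counts were not whole.

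The lipid-handling macrophage list rose in lesional myeloid-like cells, and cells of the class could only have shifted between its clusters. Inside clusters, however, the list was higher by 0.655 ± 0.361 (SD) log2 units in 6 of 6 donors (exact p = 0.03125, the smallest 6 pairs allow), against 1.33 ± 0.731 over the whole class, which argues against a shift alone. Clusters are drawn from the same genes, so that the value inside them is held down by their making, and finer shifts inside a cluster stay open. Deeper lesional cells as the whole cause are argued against by 2 donors whose lesional myeloid-like cells were shallower and whose list rose by 0.834 and 2.22. Free RNA of macrophages in other myeloid-like cells was not tested for this list, so that it, a finer shift and a change inside macrophages stay open as hypotheses.

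The immediate-early and stress list was lower in lesional T and NK-like cells by 0.327 ± 0.157 (SD) log2 units in 6 of 6 donors, and such genes respond to digestion, so that a difference in handling between the biopsies may account for it. In myeloid-like cells of the same biopsies the list changed by 0.0834 ± 0.271 and was lower in 2 of 6 donors, and the difference between the 2 classes was 0.411 ± 0.370 in 6 of 6 donors (exact p = 0.03125, adjusted p = 0.334 over 214 pairs). This argues against handling that moved all classes alike, at an adjusted p that did not pass and in the most distant of 3 classes compared. Fibroblast-like and vascular endothelial-like cells lay between, at -0.0729 ± 0.256 (lower in 4 of 6 donors) and -0.0999 ± 0.507 (3 of 6). With fewer donors the list was at -0.265 in mural-like, -0.193 in gland-like and -0.072 in mast-like cells. It was at 0.12 in keratinocyte-like and 0.0734 in lymphatic endothelial-like cells. Handling that acts on T and NK-like cells more than on others and a difference in the state of the cells stay open.

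Single donors stood far from the other 5 in 7 of 30 groups of class shares tested by Dixon's Q. Its rate of about 1 in 20 by chance holds for normal values, and shares of rare classes are bounded at 0. Groups also share biopsies, so that the 7 cannot be set against that rate. In lesional biopsies the highest share was 0.718% for B and plasma-like cells, 1.08% for Schwann-like cells and 22.2% for the class named for haemoglobin genes. In non-lesional biopsies it was 1.12% for Schwann-like, 30.7% for gland-like, 5.19% for melanocyte-like and 0.146% for sebocyte-like cells. The gland-like, melanocyte-like and sebocyte-like values came from the same biopsy, that of donor 4. Sebocyte-like cells were found in no other biopsy, so that this donor stood apart by construction. Of 78 list changes tested, 4 had a donor far from the rest, all for the eccrine gland markers, whose lowest mean log2 change was -6.01 in T and NK-like, -9.03 in fibroblast-like, -8.89 in myeloid-like and -7.89 in vascular endothelial-like cells. Those 4 values belong to the donor whose non-lesional biopsy held the most gland-like cells.

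In each of 4 donors the type I interferon list was higher in lesional keratinocyte-like cells (0.880 ± 0.300, SD) and lower in vascular endothelial-like cells (-0.398 ± 0.405), a difference of 1.28 over the 4 members measured in both. Its exact p, 0.125, is the smallest that 4 donors allow, and no adjusted p passed. The cholesterol synthesis list went the other way in each of them, with -0.476 ± 0.187 in keratinocyte-like and 0.424 ± 0.322 in vascular endothelial-like cells and a difference of -0.900 over 12 members. An unnamed cluster of 1064 cells, led by macrophage and immunoglobulin genes and 3.41% of lesional cells, was found in lesional and in none of the non-lesional biopsies. It came from 1 biopsy and entered no comparison of genes except that of all cells.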

How the results depend on the processing

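The alternatives that changed the scaling, the weights, the doublet share or the processing batch, and the swaps of lesion states, were chosen after the data were seen. The planned edgeR and DESeq2 fits and the size factors of DESeq2 were not run, since the deposited values are logged and not all derive from whole counts. Shallow libraries limit the low genes, the median depth per deposited cell being 1279 UMIs in the shallowest. Of the called genes named, 249 in all, no alternative reversed the direction: 3207 values kept direction and call and 1378 kept the direction only. Most of these genes had moved the same way in every donor, which the naming rule asks of the leading ones, so that leaving out donors could not reverse them, nor could leaving out the block, with no replicate block changing the errors only. Of the 116 list calls, 579 values kept both, 314 the direction only and 6 were reversed. Shares, none of which passed, kept their sign in 142 values and changed it in 25. Of 22 named genes that did not pass, 391 values stayed so, 14 passed and 31 changed sign. The causes were not tested, except that leaving out donors or cells leaves fewer, and that lifting the filter tests more genes. Lifting the filter also lowered the prior degrees of freedom, the weight of the variance shared over genes. They fell from 9.73 to 1.63 in keratinocyte-like cells, 10.4 to 2.28 in fibroblast-like cells and 4.61 to 1.33 over all cells. In mast-like cells, where 10 genes still passed, they stayed infinite. More genes tested is thus not the only change that the lifted filter brings.

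With no replicate block the genes past the threshold numbered 0 in T and NK-like cells, 0 over all cells, 4 in gland-like, 0 in fibroblast-like, 810 in keratinocyte-like, 3 in lymphatic endothelial-like, 8 in mast-like, 0 in mural-like, 1 in myeloid-like and 0 in vascular endothelial-like cells, and TREM2 in myeloid-like cells kept its change of 1.31 but did not pass. Where limma gave 0, unadjusted p under 0.05 stood at 292, 598, 455, 388 and 799 genes in T and NK-like cells, all cells, fibroblast-like, mural-like and vascular endothelial-like cells. With no filter on low values 0 genes passed in T and NK-like, gland-like, fibroblast-like, keratinocyte-like, lymphatic endothelial-like, mural-like, myeloid-like and vascular endothelial-like cells and over all cells, with 918, 521, 1690, 4283, 629, 519, 1605, 1449 and 3305 at an unadjusted p under 0.05, and TREM2 (1.31) did not pass.

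A pseudocount of 1 gave 3 genes over all cells, 1 in fibroblast-like (a fall), 4 in lymphatic endothelial-like, 8 in mural-like, 119 in myeloid-like and 44 in vascular endothelial-like cells, and a pseudocount of 0.01 gave 158 over all cells, 4 in gland-like, 4 in fibroblast-like (all falls) and 34 in vascular endothelial-like cells. At least 50 cells per donor and state gave 5 in gland-like, 6 in fibroblast-like, 127 in lymphatic endothelial-like and 38 in vascular endothelial-like cells. At most 10% mitochondrial counts gave 6 in fibroblast-like and 10 in mural-like cells, and a clustering resolution of 2 gave 40 in fibroblast-like cells. The authors' donor-by-lesion average table gave 440 genes over all cells. Of the alternatives added, array weights gave 192 in T and NK-like cells, 460 over all cells, 13 in gland-like, 428 in fibroblast-like, 58 in lymphatic endothelial-like, 54 in mural-like and 795 in vascular endothelial-like cells. Summed estimated counts gave 12 in T and NK-like cells, 857 over all cells, 201 in fibroblast-like, 26 in mast-like, 498 in myeloid-like and 190 in vascular endothelial-like cells. Median centring gave 185 over all cells, 5 in gland-like, 47 in fibroblast-like, 38 in lymphatic endothelial-like and 12 in mural-like cells.

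In donors 1, 4, 5 and 6 alone, 0 genes passed in limma in T and NK-like cells, 3 over all cells, 52 in fibroblast-like, 472 in keratinocyte-like (donors 1 and 6 only) and 5 in vascular endothelial-like cells, and TREM2 changed by 1.28 and did not pass. In donors 2 and 3 alone, 17 passed in T and NK-like cells, 1416 over all cells, 23 in fibroblast-like, 128 in keratinocyte-like, 63 in myeloid-like and 15 in vascular endothelial-like cells, and TREM2 changed by 1.39 and did not pass. Leaving out each donor in turn gave 5 to 10 genes in T and NK-like cells, 3 to 241 over all cells, 1 to 11 in gland-like, 4 to 43 in fibroblast-like, 993 to 1621 in keratinocyte-like, 12 to 127 in lymphatic endothelial-like, 1 to 296 in mural-like, 118 to 219 in myeloid-like and 29 to 84 in vascular endothelial-like cells.

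List calls at a preset correlation numbered 5 in T and NK-like cells, 20 over all cells, 4 in gland-like, 13 in fibroblast-like, 12 in keratinocyte-like, 9 in lymphatic endothelial-like, 13 in mast-like, 12 in mural-like, 13 in myeloid-like and 15 in vascular endothelial-like cells. With an estimated correlation 1 held in T and NK-like cells and 0 in every other class and over all cells. With fry 9 held over all cells, 2 in vascular endothelial-like cells and 0 elsewhere, and with no replicate block 1 in T and NK-like, 2 in gland-like and 8 in fibroblast-like cells. Without each donor in turn 2 to 7 passed in T and NK-like, 2 to 11 in gland-like and 8 to 18 in mast-like cells. Without donor 4 the eccrine gland list changed direction in T and NK-like (adjusted p from 0.000234 to 0.700 over the donors left out), lymphatic endothelial-like (4.04e-69 to 0.341), mural-like (9.02e-15 to 0.631) and myeloid-like cells (0.00124 to 0.883), as did the MHC class II (0.00217 to 0.535) and endothelial activation lists (1.40e-08 to 0.931) in gland-like cells.

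Among shares, in percentage points of lesional minus non-lesional, donors 1, 4, 5 and 6 gave -3.29 for fibroblast-like, 2.45 for keratinocyte-like and -0.0798 for mast-like cells. Donors 2 and 3 gave -0.0475 for B and plasma-like, 0.000762 for Schwann-like, 0.191 for lymphatic endothelial-like, -4.16 for red blood cell-like (the class named for haemoglobin genes, whose leading genes bear out the name only in part), 0 for sebocyte-like and 1.83 for vascular endothelial-like cells. Resolution 2 gave -0.174 for fibroblast-like cells, shares outside the keratinocyte-like class 0.00344 for lymphatic endothelial-like cells, and log2 shares 0.124 for lymphatic endothelial-like, -0.0588 for red blood cell-like and 0.00758 for vascular endothelial-like cells. Without each donor in turn the range was -2.05 to 3.64 for fibroblast-like, -0.305 to 0.191 for lymphatic endothelial-like, -0.0590 to 0.173 for mast-like, -1.76 to 3.84 for red blood cell-like, -0.0291 to 0 for sebocyte-like and -2.23 to 0.179 for vascular endothelial-like cells.

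Of the genes that did not pass, SELE in vascular endothelial-like cells changed sign most often, at -0.0550 with array weights, -0.11 with summed counts, -0.0372 in donors 1, 4, 5 and 6, -0.0659 with median centring, -0.27 with 50 cells, -0.0217 with 10% mitochondrial counts and from -0.11 to 0.24 without each donor in turn. VCAM1 was at -0.51 with array weights, -0.21 with 50 cells and -0.12 to 0.43 without each donor. In T and NK-like cells IL17A was at -0.29 in donors 1, 4, 5 and 6, -0.16 with a pseudocount of 1 and -0.45 to 0.51 without each donor, GZMB at -0.22, -0.0521 and -0.24 to 0.54 in the same settings, and FOXP3 at -0.0053 with 50 cells and -0.0053 to 0.24 without each donor. In fibroblast-like cells CXCL12 was at 0.024 with summed counts and 0.15 with 50 cells, COL1A1 at -0.0896 in donors 2 and 3 and CCL19 at -0.022 to 1.34 without each donor. In myeloid-like cells CXCL8 was at -0.35 with summed counts, -0.21 in donors 2 and 3 and -0.16 to 0.42 without each donor, CCL2 at -0.0377 with a pseudocount of 1 and IL1B at -0.84 to 0.0101 without each donor.

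Of the same genes 14 values passed under an alternative. In keratinocyte-like cells these were S100A8 with a pseudocount of 1 (3.94), without donor 6 (3.24), with median centring (4.25) and in donors 2 and 3 (3.50), and S100A9 without donor 6 (2.99), with median centring (4.05) and in donors 2 and 3 (3.18). In fibroblast-like cells they were CCL19 with 50 cells (1.97) and MMP1 (3.70) and MMP3 (3.23) in donors 1, 4, 5 and 6. In myeloid-like cells they were CXCL10 without donor 1 (1.71), CCL2 without donor 4 (1.21) and APOE with summed counts (3.35) and in donors 2 and 3 (1.38).

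Swapping the lesion states within donors tests whether chance alone gives as many genes. In 5 comparisons 1 of 32 arrangements, the real one, gave as many, the smallest share that 32 arrangements allow. In T and NK-like cells 6 genes stood against at most 1 in any other arrangement, over all cells 97 against 4. The counts were 14 against 1 in fibroblast-like, 248 against 6 in myeloid-like and 89 against 0 in vascular endothelial-like cells. This argues against chance in each of the 5 but does not exclude it, with no adjustment over the comparisons made. The arrangements were too few for a share under 0.05 elsewhere: 8 in keratinocyte-like cells (1843 against 0) and 4 in gland-like (8 against 0), lymphatic endothelial-like (18 against 6), mural-like (21 against 0) and mast-like cells, where 2 of the 4 gave the real 12.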

Other observations

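The subtype comparison below and the genes shared by several classes were chosen after the results were seen.

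In the subtype tables, which the authors pooled over the same donors and both lesion states and which have no replicates, 86.1% of the 1291 falling genes of keratinocyte-like cells were highest in granular keratinocytes, the layer below the cornified one, against 46.3% of all genes tested. Of the 552 rising genes, 65.2% were highest in basal and 22.8% in hair follicle keratinocytes, against 24.6% and 6.55%. Of the 59 rising genes of vascular endothelial-like cells, 37 were highest in endothelial subtype 5 (62.7%, against 14.7% of the genes tested). Among them COL4A1 was at 1680 CPM there and 619.1 in the next subtype, COL4A2 at 1301 and 514.5, HSPG2 at 1211 and 827.9, and THBS1 at 231.3 and 135.6. In fibroblast-like cells 6 of the 10 falling genes were highest in subtype 4 (40% of the genes tested) and 3 of the 4 rising ones in subtype 1 (19.8%). Of the 5 genes that fell in T and NK-like cells, 4 were highest in NK cells, as were 37.6% of the genes tested, and CXCL13 was highest in the column of naive and Th17 cells, at 130.2 CPM. No test was run on these shares.

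The complement genes C1R and C1S, which start the classical pathway, rose in keratinocyte-like cells by 1.85 ± 0.178 and 1.20 ± 0.158 (n = 4, limma adjusted p = 6.76e-05 and 0.000373), where CD55, which shields cells from complement, fell by 1.49 ± 0.162 on the log2 scale. Of the 5 complement genes measured there 2 rose and 1 fell, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.0331, and 0.414 with an estimated correlation). C1R also rose in lymphatic endothelial-like cells (2.40) and mural-like cells (1.59), each in 3 donors. Fibroblast markers rose in 2 of these classes as well, COL3A1 by 0.68 and DCN by 0.50 in keratinocyte-like and COL3A1 by 2.60 and COL1A2 by 1.55 in lymphatic endothelial-like cells. DGAT2, which makes triglycerides, fell by 1.64 ± 0.166 in keratinocyte-like cells, as did the fatty acid enzymes FASN (-0.67) and ELOVL6 (-0.80), while the sebaceous lipid list did not pass (adjusted p = 0.231). In myeloid-like cells OSM, a cytokine of the IL-6 family, rose by 1.28 ± 0.225, and CLEC4E, a receptor for mycobacterial and fungal glycolipids, by 1.71 ± 0.315 (n = 6). Inside the clusters of that class the monocyte and neutrophil list differed by 1.16 ± 0.576 (SD), higher in 6 of 6 donors, and the Langerhans and dendritic cell list by -0.308 ± 0.252, lower in 6 of 6 (exact p = 0.03125 for both), and the MHC class II list differed by -0.0445 ± 0.289 (exact p = 0.8125).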
